A study of Mus musculus with 2 samples.

How the data were processed

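The labels describe 2 samples, a normal mouse brain and a normal mouse heart, each a 5 µm section of FFPE tissue from which total RNA was copied in place with random primers and read out on an array of spots. Each sample is 1 library, so each tissue has 1 library and no replicate. Per the submitters' processing notes, reads were aligned and counted with STARsolo (version not given in the sources used here) against genome build mm39. The deposited values are counts: per section a sparse matrix of whole numbers, with a list of 40276 features and a list of 4992 barcodes of 16 bases that is the same in both sections. The sources used here do not state whether reads with the same molecular tag were merged, whether reads in introns were counted, or whether strand was used, so the values are called counts. Of the features, 23 are parts of the ribosomal DNA unit and 40253 are Ensembl gene IDs, of which 1574 carry their ID as symbol. The reference held here, GENCODE mouse release 21 on GRCm 38, is older than the build of the files. It was used only to look up by gene ID the biotype, the gene span, the chromosome name and which genes overlap on a strand, and 35551 of the IDs were found in it. Spot positions and images were not used here.

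Barcodes with at least 500 counts and 200 genes were kept as spots over tissue: 4080 in brain and 3726 in heart, with 37143546 and 44613867 counts. For genes per spot each kept spot was thinned at random to 2800 counts (seed 1), the 25th percentile of the shallower section rounded down, and 3060 and 2939 spots were deep enough. Counts were summed over kept spots and scaled to the library total as CPM. A value has an exact Poisson interval, a share of counts an exact binomial interval and a ratio of sections an exact conditional binomial interval, all at 95% and for counting error only. These intervals take each count as a separate molecule. Where a section had no count, the ratio was bounded against a floor of 3 counts. A feature counted as higher in a section with a ratio of at least 4-fold and at least 20 CPM there. The median log2 ratio of features with a mean of at least 5 CPM is given as the shift of a scaling. No test was run and no p-value is given, since a section is the unit and each tissue has 1.

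Gene lists were fixed before the data were examined, as were the size rule, the settings and most alternatives. The 40 lists cover pan-neuronal, excitatory neuron, inhibitory neuron, myelin, oligodendrocyte precursor, astrocyte, microglia and choroid plexus genes; cortex, hippocampus, thalamus, striatum, hypothalamus, cerebellum and midbrain dopamine genes; sarcomere, ventricular, atrial, conduction system, cardiac stress, fibroblast, endothelial and smooth muscle genes; fatty acid oxidation, glycolysis, nuclear-encoded oxidative phosphorylation, muscle isoforms of mitochondrial proteins, mitochondrially encoded and ribosomal protein genes; erythrocyte, leukocyte, skeletal muscle, fat, mesothelium and meninges, and epithelium, liver and skin genes; and immediate early, small structured RNA, long non-coding RNA, ribosomal-RNA-overlapping and Y-linked genes. For each list the median log2 ratio of brain over heart, with 0.5 counts added to each sum, was set against 10000 random lists of the same size drawn from 20 bins of mean expression. Genes were named by a rule: the 12 largest ratios in each direction at 100 CPM or more; the 10 highest CPM in each section; the 8 largest ratios in each direction among non-coding RNAs at 50 CPM or more; from each list 2 to 4 members with the highest CPM, and members that go against their list by at least 2-fold at 20 CPM or more; and per region the 3 listed genes with the largest fold at 50 CPM or more.

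Within each section kept spots were grouped on log depth-scaled counts of the 2000 most variable genes, with 20 principal components, 15 neighbours and Leiden clustering at a resolution of 0.6. All listed genes and mitochondrial and ribosomal RNA were left out of the grouping, so that the lists can be described across regions. Regions are called by number and leading genes, and folds compare the summed counts of a region with the rest of the section. Spearman rho between list sums across thinned spots was set against 1000 random pairs of lists of the same size. Their members were drawn from the unlisted protein-coding or long non-coding genes nearest in mean expression. Barcodes below the spot threshold were summed as a measure of background. As a second measure of background, counts of 1488 olfactory and vomeronasal receptor genes were divided by their span of 12814 kb.

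The steps were tested on simulated data. Of 50 genes set to 8-fold and 50 set to 16-fold all passed the size rule. None of 50 set to 2-fold, none of 50 set to 4-fold and none of 5121 genes without a difference did. After scaling to the total, the median estimated ratios of genes set to 2-fold, 4-fold, 8-fold and 16-fold were 1.684, 3.368, 6.763 and 13.47. Genes set to 4-fold thus lay under the rule by construction, and their result says nothing about genes at 4-fold. Ratio intervals held the true value for 86.0% to 98.0% of genes with a difference and 95.8% of the others. Clustering of 900 simulated spots of 3 profiles had an adjusted Rand index of 0.997, but 900 spots of 1 profile were split into 2 clusters. Of random lists 4.50% fell outside the range of chance, and of pairs of lists without structure 5.26% in brain and 4.74% in heart.

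Alternatives covered all barcodes, at least 2000 counts or Otsu's threshold for spots; CPM outside mitochondrial, small structured and ribosomal RNA; scaling by the trimmed mean of log ratios; the mean of the CPM of each spot; subtraction of the profile of barcodes off tissue; floors of 100 CPM or of 10 counts; a 2-fold rule; a pseudocount of 5; clustering at resolutions 0.3 and 1.2, with 1000 genes, with the listed genes, on thinned spots and by k-means; and lists across spots without thinning. Subtraction of the receptor gene density, leaving out the shallowest region of each section and thinning only the counts outside ribosomal RNA (to 1500) were added after the data were seen. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. No deconvolution into cell types and no doublet caller was run, since a spot can hold several cells. Some genes that the naming rule selects are not reported here.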

Results

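The series measured total RNA in place on formalin-fixed, paraffin-embedded (FFPE) mouse tissue, a form of tissue in which RNA is crosslinked and broken, with random primers on an array of barcoded spots. It holds 1 section of normal brain and 1 section of normal heart, each 5 µm thick, and 1 library was made from each (n = 1 per tissue). The labels name no treatment of the animals, so the comparisons are brain against heart and, within each section, groups of spots against each other. The brain library held 37300503 counts and the heart library 44768698, spread over the same 4992 spot barcodes and 40276 features. Spot positions were not used here, so spots were grouped by expression alone and no region was placed on the tissue. With 1 library per tissue no difference has a replicate check, and no p-value is given. Every interval is a 95% interval for counting error only. It covers that error only if each count is a separate molecule, which the sources used here do not state.

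Spots over brain recorded more genes than spots over heart when thinned to the same total of counts, which includes ribosomal RNA, but not when thinned outside ribosomal RNA. At 2800 counts of every kind the median was 1222.5 genes per spot in brain (quartiles 1171 and 1277, 3060 spots) and 846 in heart (quartiles 736 and 979, 2939 spots), and 1020 and 787 spots were too shallow to thin. At 1500 counts outside ribosomal RNA, a setting chosen after the data were seen, the medians were 1086 in brain (3180 spots) and 1083 in heart (2798 spots). Without thinning the order turned, with medians of 2086 genes in brain and 2135.5 in heart. Barcodes with at least 500 counts and 200 genes numbered 4080 in brain (81.7% of barcodes, median 5981 counts, quartiles 2801 and 10403) and 3726 in heart (74.6%, median 9049.5 counts, quartiles 4100 and 16509).

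Ribosomal RNA took a larger share of the heart library and protein-coding genes a larger share of the brain library. Nuclear ribosomal RNA made up 48.5% of heart counts (exact binomial interval 48.50 to 48.53) and 31.1% of brain counts (31.09 to 31.12), and the 28S subunit RNA alone gave 432445 CPM (counts scaled to the library total) in heart and 274467 in brain. Protein-coding genes gave 57.0% of brain counts (57.03 to 57.06) and 36.2% of heart counts (36.23 to 36.26). The 13 proteins encoded by the mitochondrial genome, all subunits of the respiratory chain or ATP synthase, gave 1.52% of heart counts and 0.622% of brain counts, and mitochondrial ribosomal RNA 6.11% and 3.83%. Small non-coding RNA gave 0.295% in brain and 0.131% in heart. Long non-coding RNA gave 3.995% of brain counts and 3.48% of heart counts, but over the counts outside ribosomal RNA the order turned, to 6.35% in brain and 8.26% in heart. Mitochondrial tRNA (0.474% and 0.416%) turned in the same way, to 0.754% and 0.985%. Replication-dependent histone genes, whose messages lack poly(A) tails, had shares with overlapping intervals (0.00594% in brain, 0.00569 to 0.00619, and 0.00583% in heart, 0.00561 to 0.00606), and 0.00944% and 0.0138% over the counts outside ribosomal RNA. Protein-coding genes stayed higher in brain over those counts (90.7% against 86.0%).

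**Figure D1:**
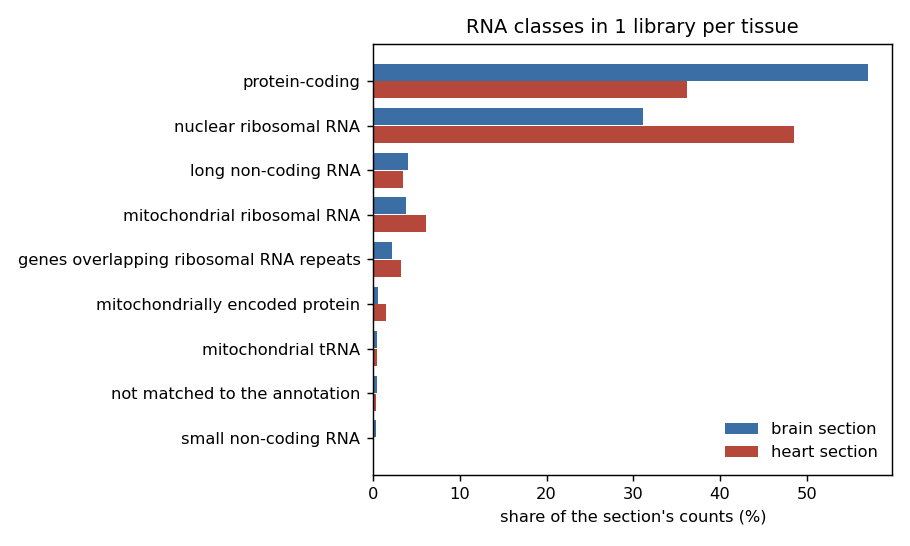
Share of the counts of kept spots (%) in each RNA class for the brain section (blue) and the heart section (red), 1 library each; classes under 0.1% in both sections are left out. Nuclear ribosomal RNA takes 48.5% of heart counts and 31.1% of brain counts.

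The lists of neuronal, myelin and astrocyte genes had medians higher in the brain section, and the list of sarcomere genes a median higher in the heart section. Among genes with at least 100 CPM in brain, the largest ratio belonged to Snhg11, a host gene of a small nucleolar RNA, at 577 CPM in brain and 0.941 in heart (613-fold, interval 453 to 850). Snap25, a SNARE protein of synaptic vesicle release, was 121-fold higher in brain (107 to 136) and Chgb, a granule protein of secretory cells, 140-fold (103 to 197). In the other direction Myh6, the alpha cardiac myosin heavy chain, reached 4126 CPM in heart and 2.32 in brain (1782-fold, 1443 to 2228), Actc1, cardiac actin, was 1670-fold higher (1069 to 2773), Myl2, the ventricular regulatory light chain, 995-fold (674 to 1538), and Ttn, the giant spring protein of the sarcomere, 589-fold (553 to 629). The beta globin gene Hbb-bs had 14803 counts in heart and 1 in brain, a ratio of 12324 (2212 to 486817).

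Of 6345 features with at least 20 CPM in either section, 1092 were at least 4-fold higher in brain and 343 at least 4-fold higher in heart, so 76.1% of these were higher in brain. That split rests on the scaling. The median log2 ratio of brain over heart across 11925 features with a mean of at least 5 CPM was 0.43, and with CPM taken outside ribosomal, mitochondrial and small structured RNA it was -0.19. On that scaling 803 features were higher in brain and 886 in heart (47.5% in brain), and 714 and 343 of them were among those of the first scaling. The floor of 20 CPM was kept over this smaller total, so it admitted features with fewer counts than on the first scaling. Genes with small ratios changed sides as well: Malat1, Dmd, Prox1, Tbx3, Jun, P2ry12, Slc18a2 and the glycolysis genes Hk1, Gpi1 and Pkm were higher in brain on the first scaling and higher in heart on this one.

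**Figure D2:**
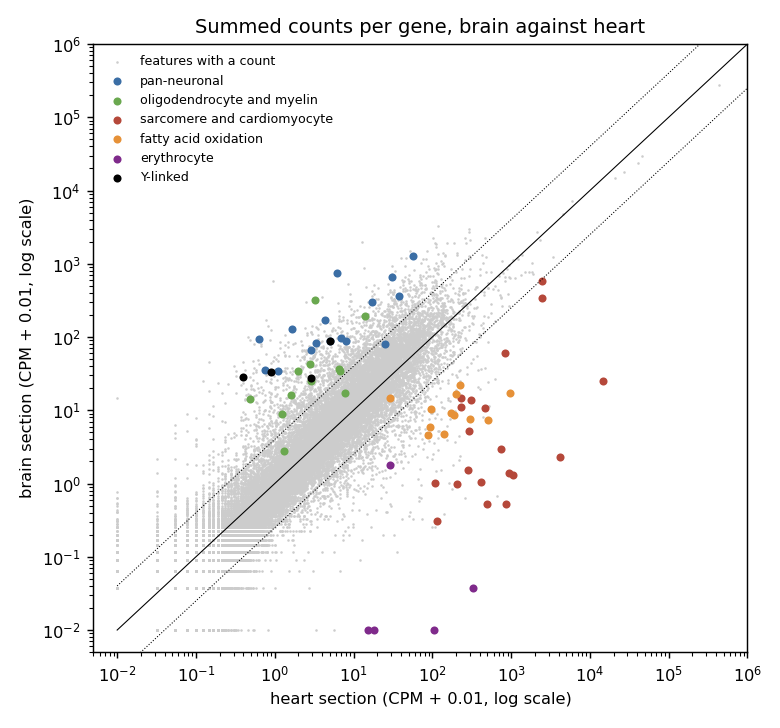
Summed counts of each feature in the heart section (x axis) and the brain section (y axis), in CPM plus 0.01 on log scales, with 6 fixed gene lists in colour; the solid line marks equal CPM and the dotted lines 4-fold differences. The pan-neuronal genes lie above the solid line and the 20 sarcomere genes below it.

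All 16 pan-neuronal genes were higher in brain and 15 passed the size rule, with a median log2 ratio of 4.49, above all 10000 random lists of the same size matched on mean expression. Syt1, the calcium sensor of transmitter release, had 1268 CPM in brain and 56.8 in heart, Map2, a dendritic microtubule protein, 650 and 30.8, and Rbfox3, the neuronal splicing factor NeuN, 365 and 37.97. Nap1l5, Kif5a (a neuronal kinesin motor), Scn2b (a sodium channel subunit) and Eno2 (neuronal enolase) were also among the 12 largest ratios, at 225-fold, 87.8-fold, 80.5-fold and 78.7-fold. Excitatory neuron genes had a median of 4.54, with 7 of 8 past the rule. Grin2b, an NMDA receptor subunit, was 25.6-fold higher in brain (24.5 to 26.7), Camk2a, the calcium-dependent kinase of synapses, 28.01-fold (26.1 to 30.1), and Slc17a7, a vesicular glutamate transporter, 21.2-fold (18.5 to 24.3). Inhibitory neuron genes had a median of 2.67, and Gad1 and Gad2, which make GABA, were the 2 of 9 past the rule at 14.3-fold and 10.5-fold. Slc32a1 and Pvalb were higher in brain at 9.72 and 12.1 CPM, under the floor of 20 CPM.

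Glial lists followed, with the exception of microglia. Myelin genes had a median log2 ratio of 3.22 and 7 of 12 past the rule, among them Mbp (14.1-fold, 13.0 to 15.4), Mobp (15.4-fold, 12.8 to 18.6) and Ugt8a (5.54-fold, 4.88 to 6.31). The astrocyte list had a median of 2.89 and 6 of 11 past the rule. The glutamate transporters Slc1a2 and Slc1a3 were 64.2-fold (59.3 to 69.7) and 7.71-fold (6.97 to 8.55) higher in brain, Atp1b2 12.3-fold and Slc4a4 2.73-fold, while the gap junction gene Gja1, which cardiomyocytes use as well, was 2.34-fold higher in heart (2.21 to 2.49). Oligodendrocyte precursor genes had a median of 2.07 with none of 6 past the rule. Olig1 had 325 counts in brain and 3 in heart (ratio 130, 44.1 to 634) and Gpr17 was 9.52-fold higher in brain, but Pdgfra and Cspg4, which stromal and mural cells share, were 1.40-fold and 1.49-fold higher in heart. Microglia genes differed little between the tissues, with a median of -0.13 and none of 10 past the rule, and the sign turned to 0.13 when each spot weighed the same. Cx3cr1 had 15.9 CPM in brain and 17.3 in heart, Csf1r 7.65 and 11.4, and P2ry12 7.94 and 7.02.

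Hypothalamus, striatum, cortex and hippocampus genes were higher in brain than random lists, while thalamus, cerebellum and midbrain dopamine genes lay within the range of random lists. Hypothalamus genes had a median log2 ratio of 4.05 with 4 of 10 past the rule, led by Pmch, the precursor of melanin-concentrating hormone (342-fold, 157 to 934), with Ahi1 (10.7-fold), Nnat (16.7-fold) and Hap1 (21.3-fold). Striatum genes had a median of 2.33 with 1 of 10 past the rule, the phosphodiesterase Pde10a (6.83-fold, 6.58 to 7.09). Rgs9 was 2.83-fold higher in brain, and Rarb was 1.35-fold higher in heart. Cortex genes had a median of 1.95 (3 of 10), with Rorb at 5.39-fold, Mef2c at 3.44-fold and Rasgrf2 at 3.25-fold, and hippocampus genes 1.91 (4 of 10), with Hpca, a neuronal calcium sensor, at 36.7-fold, Cpne6 at 60.4-fold, Ociad2 at 11.8-fold and Prox1 at 1.48-fold. Choroid plexus genes had a median of 1.30 with 2 of 10 past the rule. Those were Ttr, the thyroid hormone carrier transthyretin (176-fold, 127 to 252), and Enpp2 (13.8-fold), with Kl at 5.38-fold and Clic6 at 2.52-fold below the floor. Thalamus genes had a median of 1.33 (4 of 10, percentile 91.4 among random lists), with Ntng1 at 8.21-fold, Adarb1 at 3.05-fold, Rora at 2.08-fold and Plekhg1 at 1.77-fold. Cerebellum genes stood at 0.43, turning to -0.19 on the scaling outside ribosomal RNA. Itpr1, Calb1 and Zic2 of that list were 2.60-fold, 16.6-fold and 14.8-fold higher in brain and Car8 3.09-fold higher in heart. Midbrain dopamine genes were low in both sections, with a median of -0.31 (0.13 after a background density per kb of gene span was subtracted), Th at 2.34 and 3.36 CPM, Slc6a3 at 2.40 and 3.38, Slc18a2 at 3.58 and 3.14 and Ddc at 11.6 and 12.6.

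Each of the 20 sarcomere and cardiomyocyte genes passed the size rule in heart, with a median log2 ratio of -7.62. Tnni3 and Tnnt2, cardiac troponins, were 980-fold and 668-fold higher in heart, Pln, the phospholamban brake on calcium uptake, 816-fold (616 to 1107), and Mybpc3, the myosin binding protein, from 1.05 CPM in brain to 420 in heart (interval of the ratio 292 to 563). The calcium handling genes Atp2a2 and Ryr2, which neurons also express, were 7.25-fold and 4.18-fold higher, from 337 and 582 CPM in brain. Ventricular genes had a median of -2.01, with Myl2 the 1 of 4 past the rule and Irx4, Irx5 and Hey2 at 4.06, 3.74 and 3.65 CPM in heart. Atrial genes had a median of -3.08 with 4 of 9 past the rule, namely Nppa, atrial natriuretic peptide (177-fold, 101 to 344), Myl7 (175-fold, 84.9 to 437), Myl4 (8.49-fold) and Tbx5 (7.90-fold), while Dkk3 was 2.43-fold higher in brain. Cardiac stress genes had a median of -5.21 with 3 of 5 past the rule. Xirp2 had 513 CPM in heart and 24.7 in brain, Myh7, the beta cardiac myosin heavy chain, 85.9 and 2.32, Ankrd1 71.5 and 0.619, and Acta1 19.5 and 1.32. The conduction system list had a median of 1.05, within the range of random lists (-0.64 to 1.11), and 1 of 6 past the rule, in brain. Cntn2, an axonal adhesion molecule, was 5.03-fold higher in brain, Shox2 5.81-fold and Tbx3 1.25-fold, and Gja5 1.66-fold higher in heart.

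Genes of fatty acid use separated the tissues more than those of glycolysis. Of 14 fatty acid oxidation genes 12 had counts and 11 of these passed the rule in heart, with a median log2 ratio of -4.24. Lpl, which frees fatty acids from lipoproteins, was 57.2-fold higher in heart (52.9 to 61.9), the fatty acid carrier Cd36 69.3-fold (61.5 to 78.3), Fabp3 39.2-fold (34.8 to 44.2) and Hadha, of the mitochondrial trifunctional protein, 10.1-fold (9.37 to 10.8). All 5 muscle isoforms of mitochondrial proteins passed the rule in heart (median -6.97), with Cox6a2 at 414-fold, Cox7a1 at 130-fold, Ckmt2, mitochondrial creatine kinase, at 105-fold and Slc25a4, the ADP/ATP carrier, at 5.87-fold. The 13 nuclear-encoded genes of oxidative phosphorylation were all higher in heart (median -1.72, 2 past the rule), with the ATP synthase genes Atp5a1 and Atp5b at 3.99-fold and 3.66-fold, Sdha at 2.96-fold and Ndufs1 at 2.30-fold. The 13 mitochondrially encoded genes were also all higher in heart without passing the rule (median -1.24), among them mt-Co1 at 2.80-fold, mt-Nd5 at 2.61-fold, mt-Cytb at 2.40-fold and mt-Nd2 at 2.20-fold. Glycolysis genes had a median of 0.31, which turned to -0.30 on the scaling outside ribosomal RNA. Hk1, Gpi1 and Pkm were 1.49-fold, 1.39-fold and 1.17-fold higher in brain, whereas Ldhb, Gapdh, Ldha and Aldoa were 2.52-fold, 2.38-fold, 2.26-fold and 1.76-fold higher in heart. Of 17 ribosomal protein genes 16 were higher in heart (median -0.61), with Rpl5, Rpsa and Rpl13 at 1.54-fold, 1.52-fold and 1.49-fold and Rpl4 at 1.04-fold.

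Stromal, vascular and blood genes were higher in the heart section. The fibroblast and matrix list had a median log2 ratio of -2.21 with 5 of 11 past the rule, among them Col3a1, a fibrillar collagen (14.2-fold, 12.2 to 16.6), the proteoglycan Dcn (10.2-fold, 9.02 to 11.6) and the intermediate filament Vim (7.25-fold), with Sparc at 1.24-fold. Endothelial genes had a median of -1.99 with 4 of 10 past the rule. Fabp4, a fatty acid carrier of capillaries and fat, was 445-fold higher in heart (234 to 974), the VEGF receptor Flt1 3.57-fold, Pecam1 3.37-fold and Tek 1.65-fold. Smooth muscle and pericyte genes had a median of -1.22 with none of 7 past the rule and Rgs5 at 3.39-fold, Pdgfrb at 3.12-fold, Myh11 at 1.81-fold and Mylk at 1.54-fold. The 5 erythrocyte genes had a median of -10.40 (-7.81 with genes lacking brain counts at their bound). Hbb-bt had 4730 counts in heart and none in brain, at least 1313-fold higher against a floor of 3 counts, Hba-a1 810 and none, at least 225-fold, and Alas2, which starts haem synthesis, was 15.9-fold higher. Both beta globin genes are close copies, as are both alpha globin genes, so reads may be split between them. Leukocyte genes were low (median -1.71, none of 10 past the rule), with Ptprc at 20.3 CPM in heart and 8.97 in brain, Lyz2 at 15.1 and 0.996, Cd74 at 10.8 and 0.808 and H2-Aa at 4.06 and 0.673.

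The lists of skeletal muscle, of fat and of epithelium, liver and skin stayed low over each section. Most of their members lay under 2 times the density of receptor genes per kb. These were 7 of 8 skeletal muscle genes in brain and 8 of 8 in heart. Epithelium, liver and skin genes were 6 of 6 in each section and fat genes 4 of 6, so these sums hold much background. Skeletal muscle genes summed to 13.5 CPM in heart and 7.97 in brain (median log2 ratio -0.80), with Myh1 at 3.38 and 1.21 CPM and Tnnt3 at 1.82 and 1.02. Brown and white fat genes summed to 12.1 and 8.62 (median -0.40), with Cidea at 5.74 and 4.07, and epithelium, liver and skin genes to 5.42 and 3.80 (median -0.52), with Alb at 1.79 and 1.51. Mesothelium and meninges genes had a median of -1.19, but their sum was higher in brain (76.7 against 39.9 CPM) through Ptgds, prostaglandin D synthase (3.73-fold higher in brain, 3.44 to 4.05). Slc6a13 was 1.88-fold higher in brain and Wt1 2.92-fold higher in heart. Immediate early genes had a median of 1.02, with Egr1 14.6-fold higher in brain the 1 of 10 past the rule, Arc 35.4-fold and Nr4a1 2.04-fold higher, and Jun 1.17-fold.

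The sections came from animals that differed in sex-linked RNA. Xist, the RNA that coats the inactive X, had 259 CPM in heart and 0.619 in brain (418-fold, 279 to 660). The 4 Y-linked genes all passed the rule in brain, with Uty at 17.9-fold, Ddx3y at 37.7-fold, Eif2s3y at 75.7-fold and Kdm5d at 9.54-fold, and summed to 179 CPM in brain and 9.17 in heart. Every difference between the sections is therefore also a difference between the animals. A second measured fact stands beside each list above. Genes of olfactory and vomeronasal receptors, which neither tissue should transcribe to any extent, held 2.47 counts per kb of gene span in brain and 3.85 in heart, and 11 of 16 pan-neuronal genes in heart and 11 of 20 sarcomere genes in brain lay under 2 times that density, so ratios of such genes are limited by this background.

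Non-coding RNAs with large ratios included several of known tissue use. Of 276 long or small non-coding features with at least 20 CPM, 49 passed the size rule in brain and 22 in heart, or 37 and 59 on the scaling outside ribosomal RNA. Bc1, a dendritic RNA transcribed by RNA polymerase III, was 224-fold higher in brain (160 to 324), Meg3, a maternally expressed imprinted RNA, had 1954 CPM in brain and 12.8 in heart (153-fold, 141 to 167), Rian of the same imprinted cluster was 33.7-fold higher, Miat 47.6-fold, and Snhg14, the host of a snoRNA cluster, 20.4-fold. The unnamed RNAs B230334C09Rik, Gm26871 and 5330434G04Rik were 108-fold, 30.3-fold and 23.2-fold higher in brain. In heart Mhrt, which runs antisense to Myh7, was 119-fold higher (77.8 to 193), and because the counting is not stated to use strand how many of its reads come from that gene is uncertain. Gm31251, Gm49708, D830005E20Rik, Gm13938, Hand2os1 and Gm44710 were 77.2-fold, 58.6-fold, 41.3-fold, 18.6-fold, 12.2-fold and 9.06-fold higher in heart. The fixed list of 20 long non-coding RNAs with counts had 8 past the rule in brain and 4 in heart (median log2 ratio 1.48). Neat1, the scaffold of paraspeckles, was 7.27-fold higher in heart and Airn 6.13-fold, while Malat1, the most abundant of them, had 7141 CPM in brain and 5940 in heart. Small structured RNAs had a median of 0.66, with the Y RNAs Rny1 and Rny3 4.63-fold and 3.43-fold higher in brain, Rn7sk 1.59-fold, the minor spliceosome RNA Rnu12 2.64-fold, and the vault RNA Vaultrc5 2.20-fold higher in heart. Genes that overlap ribosomal RNA repeats had a median of -0.08, among them Rn18s-rs5, an 18S copy with 27345 CPM in heart and 17645 in brain, Lars2 (1827 and 1026), Cmss1 (1235 and 1174) and Cdk8 (930 and 972).

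The most abundant features were ribosomal in both libraries. After 28S came 18S (45728 CPM in heart, 29556 in brain) and the mitochondrial ribosomal RNAs mt-Rnr2 (40400 and 23416) and mt-Rnr1 (20710 and 14883). The 18S copy Rn18s-rs5 lay between mt-Rnr2 and mt-Rnr1 in both libraries. The 5.8S RNA (4508 and 4708) was lower than Malat1 in both libraries and lower than Ttn in heart. Among the 10 highest in brain were also Kcnip4, a modulator of potassium channels (3314 CPM, 27.9-fold over heart), the splicing regulator Rbfox1 (3023 CPM, 10.3-fold) and Dmd, dystrophin (2720 CPM in brain and 2120 in heart). Ttn with 14864 CPM, Myh6 and mt-Co1 with 3418 CPM were among the 10 highest in heart.

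Within the brain section the spots fell into 13 regions, and lists left out of the grouping stood out in different regions. Region 12 (53 spots, 1.30% of spots, leading genes Sostdc1 and Tmem72) held the choroid plexus list at 68.1 times the level of the other spots (65.6 to 70.7), with Ttr at 3319 CPM (261-fold, 237 to 288), Enpp2 46.8-fold and Kl 46.7-fold. Region 7 (183 spots, Fmod and Thbd) held the fibroblast list at 8.61-fold and the mesothelium and meninges list at 38.7-fold, of which Ptgds gave 1475 of 1599 counts (3 of 6 members over 2-fold, median member log2 2.24). Ptgds was 49.5-fold higher, the GABA transporter Slc6a13 28.7-fold and Col1a2 24.6-fold. Smooth muscle, leukocyte and endothelial genes were 5.53-fold, 5.62-fold and 3.80-fold higher there as well, and receptor genes, as a measure of background, 2.45-fold. Region 6 (274 spots, Tmem88b and Trf) held the myelin list at 14.2-fold (13.8 to 14.6), with Mog 17.1-fold, Mobp 16.5-fold and Cldn11, a tight junction protein of myelin, 15.9-fold. The precursor list was 4.93-fold higher in that region and the small structured RNA list 2.42-fold (4 of 9 members over 2-fold, median member log2 0.28).

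Neuronal regions differed by territory. Region 3 (652 spots, Dlk1 and Zim1) held the hypothalamus list at 6.89-fold (6.64 to 7.14), with Pmch 207-fold, the vasopressin gene Avp 52.4-fold and Hap1 9.20-fold, and the midbrain dopamine list at 2.70-fold. Region 2 (659 spots, Amotl1 and Pcp4) held the thalamus list at 5.46-fold (5.38 to 5.55), with the kinase Prkcd 41.9-fold and Synpo2 19.7-fold, while Shox2 of the conduction list was 62.0-fold higher and inhibitory neuron genes stood at 0.19 times the rest. Region 8 (162 spots, Htr1b and Meis2) held the striatum list at 6.84-fold (6.62 to 7.07), with the adenosine receptor Adora2a 40.5-fold and the enkephalin precursor Penk 39.9-fold, and inhibitory neuron genes at 2.62-fold as a sum (3 of 9 members over 2-fold, median member log2 0.17). Region 13 (37 spots, Six3 and Lancl3) held the inhibitory neuron list at 10.04-fold (9.28 to 10.8), with Pvalb 19.1-fold, Gad1 13.8-fold and Gad2 8.83-fold.

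Cortical and hippocampal lists marked further regions. Region 5 (385 spots, Pparg and Pdzrn3) held the cortex list at 2.94-fold (2.87 to 3.01), with Lamp5 6.46-fold and Mef2c 3.81-fold. The immediate early list stood at 1.84-fold as a sum, with 2 of 10 members over 2-fold and Egr1 at 481 of 946 counts. Region 4 (550 spots, Hs3st2 and Vxn) held the cortical transcription factor Tbr1 at 3.45-fold and the secreted Dkk3 at 2.47-fold. Region 9 (145 spots, Ctxnd1 and Gpr161) held the hippocampus list at 4.15-fold (3.99 to 4.31), with Neurod6 12.2-fold, Lpl 9.44-fold and Hpca 7.74-fold. Region 11 (65 spots, Dsp and Maml2) held Prox1, a transcription factor of dentate granule cells, at 10.3-fold, Slc4a4 at 6.26-fold and Ryr2 at 3.13-fold, with nuclear ribosomal RNA at 22.5% of counts against 31.1% in the section and receptor genes at 1.45-fold. Regions 9 and 11 were also the deepest, with medians of 29076 and 33437 counts. Region 10 (74 spots, Igfn1 and Tafa2) had no listed gene of at least 50 CPM above 2.12-fold, the value of Slc17a7, with Mef2c at 1.68-fold. Region 1 (841 spots, leading gene Ahnak) had a median of 1282 counts, 0.214 times that of the section, and held Ptgds at 5.72-fold, the matrix gene Fn1 at 5.08-fold and Gfap, the astrocyte filament, at 4.01-fold, with the astrocyte list at 2.26-fold and receptor genes at 1.42-fold. As a sum the microglia list reached at most 1.80-fold, in region 7, where receptor genes stood at 2.45-fold. There 8 of its 10 members were over 2-fold, with a median member log2 of 1.78.

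**Figure D3:**
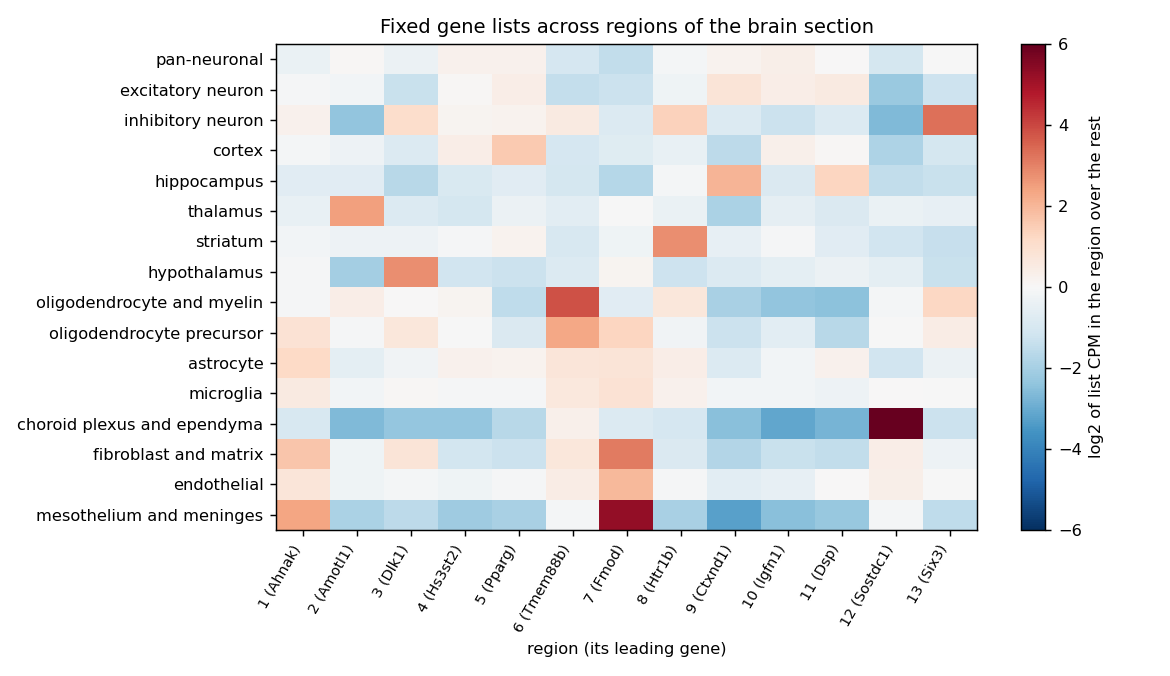
Log2 of the CPM of each fixed gene list in a region over the rest of the brain section (colour, scale from -6 to 6), for 16 lists (y axis) and 13 regions named by their leading gene (x axis). The choroid plexus list stands at 68.1 times the rest in region 12 and the myelin list at 14.2 times in region 6.

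Spot groups are not replicates and the count of regions follows from the resolution of the clustering, so the folds describe this section alone. The myelin list stood at 9.17-fold when spots were thinned before grouping and the choroid plexus list at 171-fold with a resolution of 1.2.

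Within the heart section the spots fell into 5 regions, of which an atrial and a blood-rich group stood apart. Region 4 (357 spots, 9.58% of spots, leading genes Mybphl and Prg4) held the atrial list at 16.6-fold (15.98 to 17.4), with the atrial light chain Myl7 138-fold (110 to 178), Sln, a regulator of the calcium pump, 98.9-fold and Myl4 44.8-fold. The ventricular list stood at 0.08 times the rest there as a sum (2 of 4 members lower than 0.5 times, 2 higher, median member log2 -0.78), the fibroblast list at 3.98-fold, the conduction list at 2.31-fold, the immediate early list at 2.06-fold and fatty acid oxidation at 0.38 times, with receptor genes at 1.53-fold. The fat list stood at 2.36-fold in region 4, with 4 of 6 members over 2-fold. Region 5 (281 spots, Tent5c and Slc4a1) held the erythrocyte list at 70.9-fold (68.7 to 73.2), with Hba-a1 85.3-fold, Hbb-bs 73.7-fold and Hbb-bt 72.2-fold. Sarcomere genes stood at 0.25 times the rest in that region and the pan-neuronal list at 4.07-fold, with 12 of its 16 members over 2-fold. Receptor genes were 2.91-fold higher in region 5, and the leukocyte (2.77-fold), skeletal muscle (3.49-fold), inhibitory neuron (3.14-fold), epithelium (3.35-fold), choroid plexus (2.77-fold) and myelin (2.502-fold) lists lay near that value. Sums of several other brain lists lay lower, with astrocyte, thalamus, hippocampus and cerebellum genes at 1.06-fold, 1.04-fold, 1.04-fold and 1.12-fold, precursor genes at 1.29-fold and cortex genes at 1.52-fold. Their typical members lay higher than these sums. The median member log2 was 1.425 for astrocyte, 1.517 for cerebellum, 1.569 for precursor and 1.304 for cortex genes. It was 0.754 for hippocampus and 0.384 for thalamus genes.

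Of the remaining heart regions, 1 and 3 were low in blood and atrial genes. The erythrocyte list stood at 0.0943 and 0.163 times the rest in them and the atrial list at 0.210 and 0.232 times, while folds above the rest were small. Region 1 (1631 spots, Tmem50a and Cox6b1) held mitochondrially encoded genes at 1.47-fold, with mt-Atp8 1.79-fold, mt-Nd2 1.60-fold and mt-Atp6 1.59-fold, the sarcomere list at 1.18-fold and fatty acid oxidation at 1.24-fold, and receptor genes stood at 0.467 times the rest. Region 3 (703 spots, Lrtm1 and Kcnd2) had a median of 23330 counts, with Synpo2, Mhrt and Cd36 at 1.40-fold, 1.37-fold and 1.33-fold, the smooth muscle list at 1.28-fold and receptor genes at 1.12-fold. Region 2 (754 spots, Dnah7c and Mocos) had a median of 961 counts, 0.106 times that of the section, with Cox8b, Rny3 and Cox6a2 at 2.23-fold, 1.97-fold and 1.96-fold and receptor genes at 1.54-fold. The endothelial list was highest in region 4, at 1.21-fold. Of the alternatives, thinning before grouping gave 9.86-fold and k-means 7.39-fold for the atrial list, and a resolution of 1.2 gave 9 regions.

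**Figure D4:**
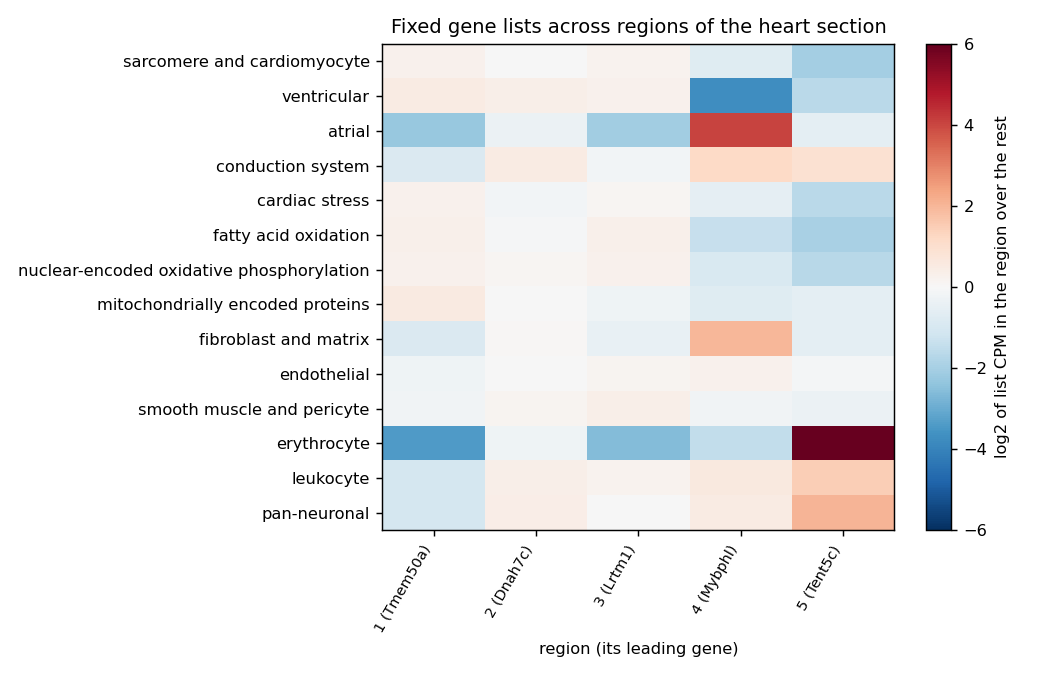
Log2 of the CPM of each fixed gene list in a region over the rest of the heart section (colour, scale from -6 to 6), for 14 lists (y axis) and 5 regions named by their leading gene (x axis). The atrial list stands at 16.6 times the rest in region 4 and the erythrocyte list at 70.9 times in region 5.

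Across spots thinned to equal depth, sarcomere genes went with nuclear-encoded energy genes in heart, and pan-neuronal and excitatory neuron genes ran against myelin genes in brain. In heart the Spearman rho of sarcomere with fatty acid oxidation genes was 0.61. The 95% range of 1000 random pairs of lists, of the same size and nearest in expression, was -0.04 to 0.39. Sarcomere with nuclear-encoded oxidative phosphorylation genes had 0.51 (random range -0.05 to 0.32). Fatty acid oxidation with nuclear-encoded oxidative phosphorylation genes had 0.43 (-0.07 to 0.31). No unlisted protein-coding or long non-coding gene in heart was as abundant as Ttn, Myh6, Malat1 or mt-Co1. Random lists for sarcomere, mitochondrially encoded and long non-coding genes were thus not matched on their most abundant members there. Mitochondrially encoded genes lay within the random range with sarcomere (0.08, range 0.02 to 0.53), fatty acid oxidation (0.19, -0.07 to 0.41) and nuclear-encoded oxidative phosphorylation genes (0.13, -0.09 to 0.32). The erythrocyte list ran against sarcomere genes (-0.37, range -0.07 to 0.34) and the atrial list against the ventricular list (-0.27, range -0.08 to 0.08). In brain excitatory neuron genes ran against myelin genes (-0.25, range -0.07 to 0.22) and with cortex genes (0.20, range -0.08 to 0.14), and pan-neuronal genes against myelin genes (-0.16, range -0.07 to 0.24). Inhibitory neuron genes lay within the range with myelin genes (0.05, range -0.05 to 0.07) and ran against thalamus genes (-0.20, range -0.06 to 0.07). Myelin genes went with small structured RNAs in brain (0.33, range -0.09 to 0.32). Mitochondrially encoded genes ran against long non-coding RNAs in both sections, with rho of -0.24 in brain (range -0.01 to 0.51) and -0.31 in heart (-0.11 to 0.33). In brain 21 of 171 pairs of lists lay above the random range and 46 below it, and in heart 19 and 54 of 190. Spots of 1 section are not independent, so rho describes these sections only.

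The profile of barcodes below the spot threshold followed the tissue in part and departed from it in part. These barcodes, which have few counts by definition, held 0.421% of brain counts (912 barcodes, median 148 counts) and 0.346% of heart counts (1266 barcodes, median 54 counts). Sarcomere genes summed to 26816 CPM in these heart barcodes and 31447 in the kept spots, and pan-neuronal genes to 2975 and 4306 CPM in brain. Nuclear ribosomal RNA made up less of their counts than in the kept spots (25.3% against 31.1% in brain, 35.7% against 48.5% in heart), and protein-coding genes more (61.1% against 57.0% and 48.3% against 36.2%). Pan-neuronal genes were higher outside the kept heart spots (665 CPM) than in them (209 CPM), as were myelin genes (110 against 50.4 CPM), and receptor genes likewise in brain (2332 against 852) and in heart (2493 against 1106).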

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

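Of the tests in this part, the one on X-linked genes near the background density was written before its result was seen. The tests on receptor genes of X, on Ttr, on the spread of ratios, on listed genes at 0 and on genes that follow 28S were chosen after the results were seen.

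Spacers of ribosomal DNA and receptor genes, which neither tissue should hold as mature RNA, had counts above the limit that a count of 0 allows. Any set with more than 3 counts passes that limit, so it says little about them. Their counts do enter the comparisons, the spacers within the class of nuclear ribosomal RNA and the receptor genes as a measure of background. The transcribed spacers of the ribosomal DNA unit, which are removed from the precursor of ribosomal RNA, had 1995 CPM in brain and 2228 CPM in heart. The intergenic spacer had 199.5 and 193.9 CPM. Genes of olfactory and vomeronasal receptors had 852 and 1106 CPM, spread over 1360 and 1393 of the 1488 genes.

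Receptor genes and genes of neurons had counts in the heart section, and in 88 protein-coding genes that were at least 16-fold higher in brain, heart counts followed gene span (Spearman rho 0.829), as did brain counts to a lesser degree (0.673). Carry-over of brain RNA at a single ratio is argued against as the only source. Heart counts as a share of brain counts differed 8.75-fold between the 5th and 95th percentile of 95 genes. That spread cannot exclude a smaller carry-over beside a background that follows span. Brain reads assigned to the heart library with their barcode are argued against as well. Barcodes with a heart count of Ttr had a mean of 0.111 brain counts of it where 270 would follow. Genomic DNA copied along with RNA may be a source, since the brain library holds Y-linked RNA and the heart library Xist, and brain over heart of receptor genes on X was 0.526 of that on autosomes (interval 0.411 to 0.668, 9 genes). The test written before missed its bound. In genes near the background density X was 0.822 of the autosomes, less than any autosome (lowest 0.896) but above the bound of 0.8 set for it. Its genes were picked by the pooled counts per kb of both sections. X genes with fewer counts from DNA could hold more RNA within that window, so the test cannot decide whether DNA is the whole cause. Another measure tried later gave 12 values (3 percentiles of brain counts per kb in each of 4 windows, X over autosomes). These ran from 0.463 to 0.761, each with X below every autosome. The Y-linked Usp9y and Zfy1 also leave part of the background open, with 1.725 counts per kb in heart and 1.96 in brain, since DNA of an animal without Y would give about none.

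Several listed genes had no count in either section. Loss of reads where a gene lies inside another gene on its strand is a candidate explanation: 76.0% of 529 protein-coding genes fully inside another gene had no count, against 1.58% of 20020 genes without overlap. Of the 6 listed genes at 0 that the annotation holds, 4 lie fully inside another gene, among them Peg13, Cpt1b and Neurod1. The remaining 2, Rmrp and Etfb, have 96.4% and 96.1% of their exons inside another gene. Receptor genes, which neither tissue should transcribe to any extent, had a count in 1360 (brain) and 1393 (heart) of 1488. This argues against absence of RNA alone as the reason for 0 counts in the 4 enclosed genes. Whether their RNA was present cannot be told from a 0.

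Genes with stretches similar to ribosomal RNA followed 28S across spots. Of 4 such genes 3, Lars2, Cmss1 and Cdk8, lay above the 95th percentile of all genes in both sections (rho 0.465, 0.469 and 0.441 in brain, 0.549, 0.491 and 0.363 in heart), and Camk1d did so in heart alone. Reads of ribosomal RNA placed in these genes may be the source, but genes not on the list, named after their values were seen, followed 28S as closely (Gm17344, Zfhx3 and Dmd at 0.535, 0.480 and 0.463 in brain, Ndufs7 and mt-Co1 at 0.562 and 0.493 in heart). Rn18s-rs5, itself a copy of 18S, was left out after a first run (0.842 and 0.834). No biological explanation was tested.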

How the results depend on the processing

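The alternatives that subtract the receptor gene density, leave out the shallowest region or thin outside ribosomal RNA were chosen after the data were seen, and the others before. No paired analysis was possible because each tissue has 1 library from a different animal. The cause was not tested for any value below unless its construction is named.

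Genes per spot reversed without thinning, to a ratio of brain over heart of 0.977, as heart spots are deeper, and moved to 1.003 with counts outside ribosomal RNA thinned. Shares of RNA classes lay close to those reported. With all barcodes, at least 2000 counts, Otsu's threshold and without the shallowest region, nuclear ribosomal RNA was 31.08%, 31.18%, 31.15% and 31.18% in brain and 48.47%, 48.62%, 48.57% and 48.64% in heart, and protein-coding genes 36.29%, 36.13%, 36.20% and 36.12% in heart. In brain they were 57.06%, 57.02% and 57.12% with all barcodes, Otsu's threshold and without the shallowest region.

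Numbers of genes past the size rule followed the rule by construction: 486 in brain and 105 in heart with a floor of 100 CPM, 1843 and 1103 with at least 10 counts and no floor, and 2506 and 762 with a 2-fold rule. With CPM outside ribosomal, mitochondrial and small structured RNA 886 genes and 59 non-coding RNAs were higher in heart. By construction the larger ribosomal share of heart leaves the total, and the floor of 20 CPM admits features with fewer counts. Subtraction of the receptor gene density gave 75 non-coding RNAs higher in brain. Other scalings and spot thresholds kept these numbers within 1.5 times. No list with a median log2 ratio of at least 1 in size and no named gene past the size rule changed sign. Of the list medians 68 moved and 329 stayed within their limits, and of the values of named genes 322 and 1459.

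A resolution of 1.2 gave 9 heart regions. Over the alternatives, agreement of spot groups with those reported (adjusted Rand index) ran from 0.6498 (resolution 1.2) to 0.843 (at least 2000 counts) in brain and from 0.323 (thinned spots) to 0.920 (resolution 0.3) in heart, so membership of heart regions depends more on the settings. Among the highest folds of lists 7 moved and 70 did not. The myelin list stood at 9.23-fold with 1000 genes, and the choroid plexus list at 171-fold with k-means. Without thinning more lists were deep enough to enter, and 45 of 406 pairs lay above and 121 below the random range in brain (21 and 46 of 171 as reported), and 33 and 86 of 378 in heart (19 and 54 of 190). Of the pairs outside the range as reported, 4 in brain and 6 in heart changed sign, none of them printed in the report. The alternative of at least 2000 counts moves nothing there, since thinned spots hold more. Below 100 counts, barcodes held 0.0468% of brain and 0.0685% of heart counts, fewer by construction. Depth limits what shallow spots show, and 1020 brain and 787 heart spots were too shallow to thin.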

Other observations

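Counts in brain lay more in genes over 300 kb, many of which encode synaptic and adhesion proteins of neurons. Protein-coding genes that span over 300 kb held 32.3% of the protein-coding counts in brain and 18.6% in heart, and those over 1000 kb 9.41% and 3.81%. The median log2 ratio of brain over heart was 1.98 for 58 genes over 1000 kb and 0.94 for 502 genes of 300 to 1000 kb, against 0.34 for genes up to 10 kb, 0.55 for 10 to 30 kb, 0.46 for 30 to 100 kb and 0.40 for 100 to 300 kb. Up to 300 kb the ratio thus did not increase steadily with span, and genes of 100 to 300 kb held a larger share in heart (26.9% against 24.7% in brain). These values were looked at after the data were seen and no explanation was tested.

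Classes of small RNA differed in level and in direction. Small nuclear RNA had 805 CPM in brain and 296 in heart, miscellaneous small RNA, which holds the Y RNAs, 1054 and 274, and ribozymes 6.95 and 0.919. Over the counts outside ribosomal RNA these stayed higher in brain, at 1279 and 702, 1675 and 649, and 11.04 and 2.18. Small nucleolar RNA (30.1 and 29.4), small Cajal body RNA (31.7 and 26.5) and microRNA genes (229 and 165) were higher in heart over those counts, at 47.9 and 69.8, 50.4 and 62.9, and 364 and 391.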
